A study of Mus musculus with 4 samples.

How the data were processed

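RNA from E18.5 mouse lung was hybridised to 4 Affymetrix 3' expression arrays, 1 per genotype (wild type, Myf5 and Myod1 double knockout) on each of 2 designs, MOE430A and MOE430B. Groups were taken from the sample titles. The deposited values are intensities on a linear scale, 1 signal per probe set. MAS5 is named in the submitters' processing notes. Its version and settings, the scanner and the detection calls are not given in the sources used here. All deposited signals were above 0, and the 2% trimmed mean of each array was 1500, so each array had been scaled on its own to 1 level. The designs are therefore not on 1 scale. The 100 probe sets carried by both designs read a median 4.03-fold higher on MOE430B, and ratios were formed only between the arrays of 1 design. Scaling of this kind assumes that the total signal does not differ between genotypes, and MAS5 signals are noisy at low intensity, which widens ratios of dim probe sets.

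From these signals, control probe sets (64 per design) were left out, and the array labelled double knockout was divided by 1 factor per design so that the median ratio of the passing probe sets was 1 (factors 1.004 and 1.008). A probe set passed when the higher of its 2 signals reached the median of all signals of its design, 787.4 on MOE430A and 855.1 on MOE430B. Signals below the 25th percentile of the design, 283.8 and 278.1, were then set to that floor, so a ratio with 1 signal below the floor is a lower bound and is given as at least N-fold. Such genes entered list medians at their bound. Probe sets passing numbered 12203 and 12892.

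Probe sets were named through GEO's platform annotation. On MOE430A, 20380 probe sets paired with 1 gene, 691 with several and 1555 with none. On MOE430B the numbers were 14661, 245 and 7605. Entrez identifiers of 20351 and 14486 of the 1-gene probe sets matched the RefSeq gene table of assembly GRCm38.p6, and no symbol needed to be updated. The table was used for names only, and no coordinates are given because the arrays' annotation names no build. A gene was represented by its passing probe set with the highest mean log2 signal over both designs. Because shared probe sets read higher on MOE430B, this choice favours its probe sets. Where the passing probe sets of a gene differ in direction, the text gives their values or range. Signals named in pairs are in the order wild type, double knockout, the latter after rescaling.

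With 1 array per genotype and design there is no test. Genes were counted at 2-fold. For 39 gene lists fixed before the data were examined, the median log2 ratio was set against 10000 random lists of the same size, matched on mean signal in 20 bins, and lists with fewer than 3 measured genes were not compared, a limit set after the values were seen. The random lists were not matched on design, although log2 ratios of genes spread more on MOE430B (SD 0.69) than on MOE430A (0.45). Named genes followed a rule fixed beforehand. Among genes with a signal at or above the 75th percentile, both signals at or above the floor, all passing probe sets in 1 direction and 1 gene name, it took the 12 with the largest log2 ratio in each direction. It also took up to 4 members of each list at that signal, the 2 highest and 2 lowest, and both targeted genes. A gene with 1 signal below the floor is given only as at least N-fold. Other names are said to have been chosen after their values were seen.

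The spread of 1 log2 ratio was estimated from the 100 shared probe sets (SD of the difference 0.346, divided by the square root of 2). The steps were tested on simulated arrays for the comparison of double knockout with wild type, with noise per signal level taken from pairs of probe sets of 1 gene. This noise includes real differences between probe sets. The run covered 12533 genes, but changes were planted only in genes with high signal, where this noise is smaller. Of those, 95 of 100 genes changed by 1.5 on the log2 scale and 100 of 100 changed by 3.0 were recovered past 2-fold. Recovery of changes in dimmer genes was not tested. Another 20 simulated pairs held noise alone. Lung cell type lists were compared by a Kruskal-Wallis H over 11 lists, each gene counted once, against 10000 random deals of the genes. This test was set up after the list medians were seen, and replaced a comparison of 4 pooled lists that had been picked by their medians and was dropped for that reason. A test on 3 T cell precursor genes was dropped too. Binomial intervals are exact Clopper-Pearson intervals and cover counting error only.

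Alternatives fixed beforehand were the signals as deposited, quantile normalization, removal of a loess curve, floors at the 10th percentile and at the median, no filter, a filter at the 75th percentile, the median over a gene's probe sets, leaving out probe sets that may cross-hybridise, and each design alone. Placing both designs on 1 scale through the shared probe sets was added after the data were seen. The work used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.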

Results

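The series measured messenger RNA in the lungs of E18.5 mouse embryos, shortly before birth, in wild type BALB/c embryos and in embryos lacking both Myf5 and Myod1, the myogenic regulators without which skeletal muscle does not form. The title of the series states its purpose as the part that skeletal muscle plays in lung development, and embryos without skeletal muscle do not make fetal breathing movements. Biotin-labelled cRNA from 6 µg of total RNA was hybridised to a pair of Affymetrix array designs, MOE430A with 22690 probe sets and MOE430B with 22575. There were 4 arrays, 1 for each genotype on each design, and no replicate. No test between the genotypes could therefore be made, no p-value is given, and the precision of every value is limited by the number of arrays. The labels do not say whether RNA came from 1 embryo or from a pool, or whether the arrays of a genotype shared 1 RNA sample. The sample titles give no strain. Whether the double knockout embryos were also BALB/c is not stated here, so a strain difference is not excluded. In place of a replicate error, the 100 probe sets carried by both designs gave an SD of 0.25 for 1 log2 ratio, though their ratios on the designs correlated at only 0.12 across probe sets. The SD leaves out an offset, since their ratios were a mean 0.22 lower on MOE430B than on MOE430A, which is about as large as several list medians below. Different probe sets of 1 gene spread more, with an SD of 0.35 on MOE430A, 0.67 on MOE430B and 0.58 between the designs. The log2 signals of the genotypes correlated across probe sets at 0.935 on MOE430A and 0.850 on MOE430B.

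The targeted genes were examined first. The Myf5 probe set read 110.5 in the array labelled wild type and 8.94 in the array labelled double knockout, both below the floor of 283.8, so that it gave no fold. The Myod1 probe set on MOE430A went against the labels, with a signal of 85.0 in the array labelled wild type and 1081 in the array labelled double knockout, at least 3.81-fold higher. A Myod1 probe set on MOE430B read 337.2 and 607.2, below the filter of 855.1. Where these probe sets lie relative to the deleted parts of the genes is not given in the sources used here, and a probe set outside a deleted part checks nothing. The genotypes are therefore named below as the labels give them, and every direction rests on those labels. Xist, the RNA that coats the inactive X chromosome of female cells, was 2.76-fold lower in the array labelled double knockout, with signals of 7600 and 2749. The Y-linked genes Kdm5d (286.5 and 737.4), Uty (164.9 and 653.1) and Eif2s3y (13.1 and 502.3), each by its probe set with the largest difference, read higher in the array labelled double knockout, all below the filter of 787.4 on MOE430A. The other passing Xist probe set was 3.64-fold lower. By these probe sets, Xist and the Y-linked genes differed in opposite directions, as a different share of male RNA in the samples would give. The labels do not give sex, so a difference in sex cannot be told apart from genotype. The control probe sets for 18S ribosomal RNA were a median 3.93-fold higher in the array labelled double knockout on MOE430A and 3.15-fold higher on MOE430B.

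Genes of lymphocytes were the gene group with the lowest values in the lungs labelled double knockout. Of 16 measured genes of the lymphoid list, 14 were lower and 11 of them at least 2-fold lower, with a median log2 ratio of -1.98. Random lists of the same size and signal had medians between -0.30 and 0.30 in 95% of draws. Rag1, which cuts antigen receptor genes in lymphocyte precursors, read 3308 in the array labelled wild type and 135.7 in the array labelled double knockout, at least 11.7-fold lower. Cd3d, a chain of the T cell receptor complex, was at least 9.32-fold lower. Thy1, a surface protein of thymocytes, was 7.97-fold lower (6021 and 755.3), and Satb1, a chromatin organiser of thymocytes, was 7.68-fold lower, with log2 ratios from -2.94 to -0.70 over its 5 probe sets. Cd8a, the co-receptor of cytotoxic T cells, had log2 ratios from -2.70 to -0.30 over 5 probe sets, and Ighm, the heavy chain of IgM of B cells, had 0.14, with -0.55 to 0.86 over 3 probe sets.

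The 12 genes with the largest decreases by the fixed rule were between 6.06-fold and 10.3-fold lower in the arrays labelled double knockout, and lymphocyte genes led them. Klhl6, a gene of lymphocytes, was 10.3-fold lower (3609 and 352.0). Ptprc, the CD45 antigen of all white blood cells, was 9.33-fold lower. Cd8b1, the second chain of CD8, was 8.75-fold lower, and Ikzf1, a transcription factor of lymphocyte development, was 8.02-fold lower, and at least 3.65-fold lower by its other probe set. Prss16, a serine protease of the thymic cortical epithelium, was 6.76-fold lower (4466 and 660.7), and H2-Ea, an MHC class II chain, was 6.16-fold lower. The remaining genes were Thy1 and Satb1, given above, Scrt1 (7.43-fold), Lingo1 (7.39-fold), Dact2 (7.09-fold) and Tmem247 (6.06-fold). The last 4 were each read by a single passing probe set on MOE430B. They fell below the filter when both designs were placed on a common scale through the shared probe sets. Klhl6 and Ikzf1, also read on MOE430B, stayed above the filter there, with smaller decreases.

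**Figure D1:**
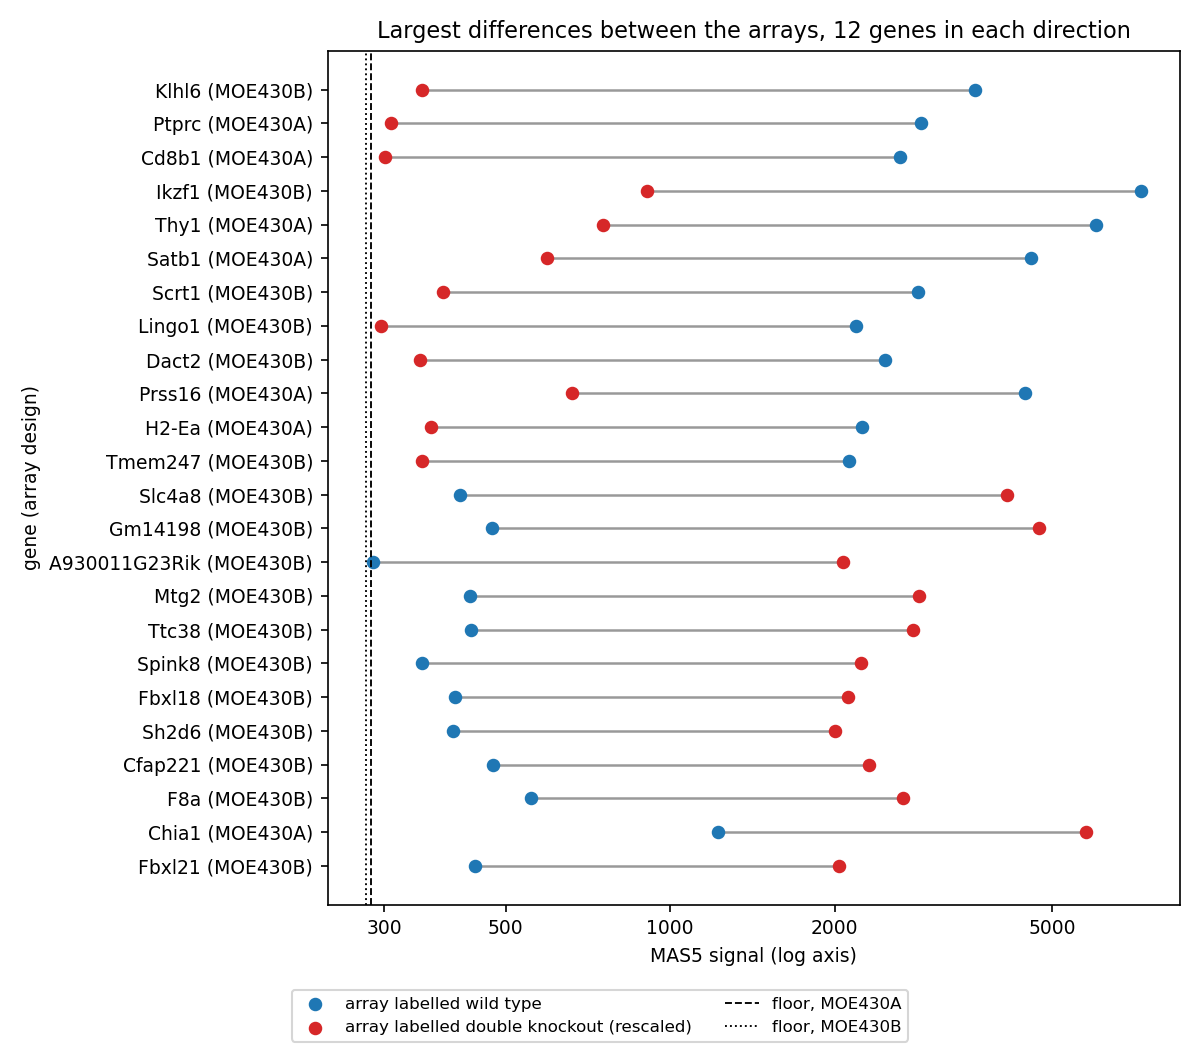
MAS5 signal on a log axis in the array labelled wild type (blue) and the rescaled array labelled double knockout (red), 1 array per point. Shown are the 12 genes with the largest difference in each direction by the fixed rule. That rule left out genes with a signal below the floor or with passing probe sets that disagreed in direction. Vertical lines mark the floor of each design. Of the 12 lower genes, 6 were read on each design, and 11 of the 12 higher genes were read on MOE430B.

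By the fixed rule, the 12 genes with the largest increases were between 4.64-fold and 10.01-fold higher in the arrays labelled double knockout. They formed no group fixed beforehand. They were Slc4a8, a sodium bicarbonate transporter (413.3 and 4137, with log2 ratios from 0.75 to 3.32 over 3 probe sets), Gm14198, A930011G23Rik, Mtg2, Ttc38, Spink8, Fbxl18, Sh2d6, Cfap221, F8a, Chia1 and Fbxl21. Of these, 11 were read on MOE430B and 11 by a single passing probe set. With both designs on 1 scale, those read on MOE430B other than Slc4a8 and Gm14198 fell below the filter. Chia1, an acidic chitinase, was the gene read on MOE430A, at 1222 and 5774, 4.73-fold higher.

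Genes of DNA replication and mitosis were lower in the arrays labelled double knockout. Of 41 measured genes of the cell cycle list, 34 were lower, 19 at least 1.5-fold and 3 at least 2-fold, and none was at least 2-fold higher. The median log2 ratio was -0.53, against -0.15 to 0.13 for matched random lists. Mcm3, a subunit of the replicative helicase, had a log2 ratio of -1.31 and was lower by all 3 of its probe sets. Pcna, the sliding clamp of DNA polymerase, had -0.97 (16680 and 8540). Kif23, a kinesin of cytokinesis, went the other way with 0.41, and the probe sets of Foxm1, a mitotic transcription factor, read 0.30 and -0.18. The lymphoid genes, whose values are given above, were lower in the same arrays. On MOE430B alone the cell cycle median was -0.22 over 10 genes, inside the range of -0.37 to 0.25 of random lists.

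**Figure D2:**
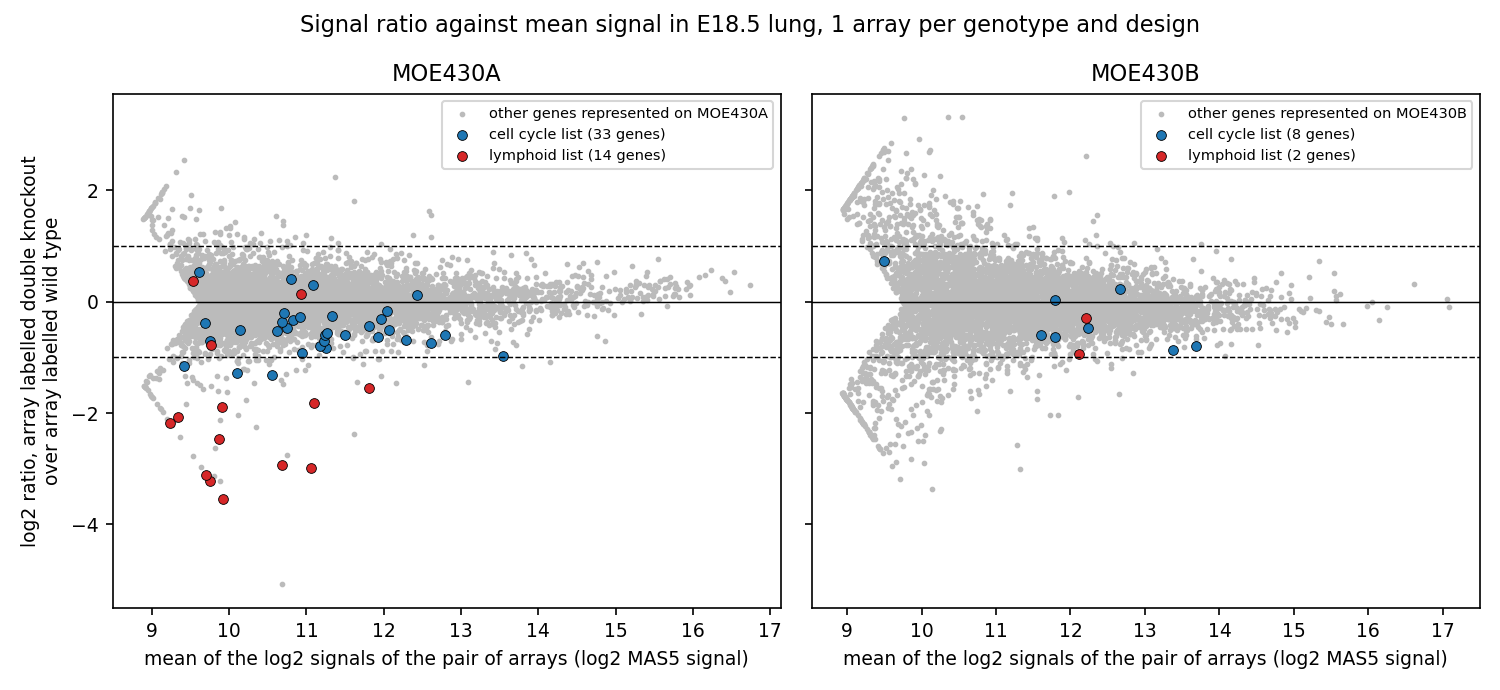
Log2 ratio of the array labelled double knockout over the array labelled wild type against mean log2 MAS5 signal, 1 point per gene, on the design that represents the gene, with dashed lines at 2-fold. Red points are the 16 lymphoid genes and blue points the 41 cell cycle genes, and the scatter of the grey points is wider at low signal and on MOE430B.

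Genes of alveolar type II cells, which make surfactant, were slightly higher in the arrays labelled double knockout. Of 23 measured genes, 22 were higher and 3 of them at least 1.5-fold, none was at least 2-fold higher, and the median log2 ratio was 0.28 against -0.17 to 0.14 for random lists. The lymphoid and cell cycle genes were lower in the same arrays. Cxcl15, the chemokine lungkine of lung epithelium, had 0.73 (32151 and 53471), and Lyz1, a lysozyme, 0.68. Fabp5 (0.00, and -0.25 by its other probe set) and Hc, complement component C5 (-0.10), were the lowest members. The surfactant protein genes Sftpc (0.53), Sftpa1 (0.52), Sftpb (0.49) and Sftpd (0.23), named here after their values were seen, all had ratios above 0. The other probe set of Sftpa1 read 0.08. The other probe set of Sftpc was at least 3.94-fold higher, but its signals were 178.9 and 1118, against 78525 and 113337 by the first. On MOE430B alone the type II median was 0.14 over 7 genes, inside its random range of -0.42 to 0.26. Type I cell genes, of the thin cells of gas exchange, had a median of 0.04 over 22 genes, inside the range of random lists. Cldn18, a tight junction protein, had 0.76 and Cav1, the caveolar coat protein, 0.63, while Col4a4 had -0.70 (-0.13 by its other probe set) and Gprc5a -0.36.

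The median of the club and secretory cell list was 0.28 over 11 genes, against -0.26 to 0.24, but 0.21 and inside the range with a loess curve removed, and the mean of the list was -0.125. Scgb1a1, the club cell secretory protein, had a log2 ratio of 0.77 (11774 and 20128) and Cbr2, a carbonyl reductase of club cells, 0.41. Members of the same list were also far lower, with Reg3g, an antimicrobial lectin, at least 8.79-fold lower and Scgb3a1 at -1.16 (21230 and 9479). Branching and epithelial signals had a median of 0.22 over 21 genes, against -0.20 to 0.18 but inside the range without probe sets that may cross-hybridise, with Lef1, a Wnt effector, at -0.71. The probe sets of Elf5 read 0.85 and -0.02. On MOE430B alone this median was -0.07 over 6 genes. Ciliated cell genes had a median of -0.02 over 16 genes, inside the random range.

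In the mesenchyme, 17 of 22 measured genes were higher in the arrays labelled double knockout, 2 of them at least 2-fold, and the median was 0.30 against -0.18 to 0.15. Hoxa5, a homeobox gene of lung mesenchyme, had 1.06 and 0.40 by its probe sets, and Tcf21, a transcription factor of lung fibroblast precursors, had 0.88 (10850 and 19966) with both probe sets near that value. Ptch1, the receptor of Hedgehog ligands, had -0.52 and Pdgfra, the PDGF receptor of myofibroblast precursors, -0.45, though the probe sets of Ptch1 ranged from -0.52 to 1.09. Smooth muscle genes had a median of 0.20 over 16 genes, against -0.21 to 0.19, with 12 higher, but 0.15 and inside the range without probe sets that may cross-hybridise. Itga8, an integrin, had 0.77 and Actg2, an actin of smooth muscle, 0.64, while probe sets disagreed for Synpo2, with -0.16 to 0.75 over 3, and for Des, with -0.09 and 0.32.

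The list of growth factors studied in lungs without fetal breathing had a median of 0.11 over 17 genes, inside the range of -0.22 to 0.18. Pdgfrb, a PDGF receptor, had 0.93 (1968 and 3749). The probe sets of Tgfb1 read 0.44 and -0.01. Igf1r and Igf1, the receptor and ligand of the IGF axis, had -0.60 and -0.50, with ranges of -1.30 to -0.05 and -0.50 to 0.03 over 4 probe sets each. On MOE430B alone the median of this list was -0.43 over 6 genes, below the random range of -0.40 to 0.26. Targets of YAP and SRF, which respond to stretch in culture, had a median of 0.04 over 24 genes. Ccn2, a matricellular protein, was at -1.13 (5030 and 2302), and Ankrd1 at -0.71. The probe sets of Cavin1 read 0.62 and -0.73, and those of Tpm2, a tropomyosin, ranged from 0.07 to 1.63. Elastic fibre genes had a median of -0.19 over 13 genes, with 9 lower, inside the range of -0.24 to 0.19, but below the range in 5 of 12 alternatives, on MOE430A alone, without a filter, with quantile normalization, with loess and with the median over probe sets, at -0.17 to -0.27. Fbln2 had -0.55 and Fbn2 -0.49, while Mfap4 had 0.56. Collagen and basement membrane genes had a median of -0.05 over 28 genes, with Lum, a proteoglycan of collagen fibrils, at -1.03 and Lama4 at 0.66 (0.02 by its other probe set). Col1a1 was at -0.78, but its other probe set read 0.04.

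The skeletal muscle list was meant to mark muscle held with the lung, but cardiac muscle genes, given below, were strong in both MOE430A arrays. How much of the skeletal list came from heart muscle was not tested, so its median does not measure skeletal muscle alone. Of 24 measured genes, 13 were lower in the arrays labelled double knockout, 4 of them at least 2-fold, and 11 were higher, 1 of them at least 2-fold, with a median of -0.04 inside the random range. Acta1, skeletal actin, had -0.73 (6305 and 3809) and Klhl41 -0.56, while Apobec2 had 0.43 and Tnni1, a slow troponin, 0.27. Mylpf, the fast myosin light chain, was at least 3.23-fold lower and Myh2, a fast myosin heavy chain, at least 3.14-fold lower. Myl1, a myosin light chain, had -1.07 (1748 and 834.4). Trdn had -1.11, but another of its probe sets was at least 3.28-fold higher. Mybpc2, a fast myosin-binding protein, was 3.76-fold higher (280.5 and 1054), with the lower signal just above the floor of 278.1. Myh4, another fast myosin heavy chain, had 0.61 (719.9 and 1100). Mybpc2 and Myh4 were each read by a single passing probe set on MOE430B. The genes from Mylpf to Myh4 were named after their values were seen. Cardiac muscle genes were strong in both MOE430A arrays, with Myl2, the ventricular myosin light chain, at 61909 and 86011. Their median was -0.13 over 29 genes, inside the range of -0.15 to 0.12 but outside that of -0.06 to 0.18 on MOE430A alone. On MOE430B alone the direction turned, with 0.45 over 3 genes above -0.48 to 0.35. Single members differed, with Tbx5 at 1.46 (0.61 by its other probe set) and Ryr2, the cardiac calcium release channel, at -0.95.

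Red cell and neutrophil genes had medians of -0.40 over 7 genes and -0.38 over 10 genes, both just below the random ranges, whose lower ends were -0.34 and -0.35. Both lay inside without a filter (0.00 and -0.15) and with the filter at the 75th percentile, and neutrophil genes also with quantile normalization and without probe sets that may cross-hybridise. Alas2, which starts haem synthesis in red cells, had -0.56, and S100a8, a calcium-binding protein of neutrophils, -0.87. Macrophage genes had a median of -0.10 over 17 genes, inside the range, and Csf1r, the receptor for the macrophage growth factor, had 0.07. Endothelial genes had a median of 0.08 over 26 genes, also inside, with Egfl7 at 0.75 (0.075 to 0.87 over 4 probe sets) and Pecam1 at -0.34.

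**Figure D3:**
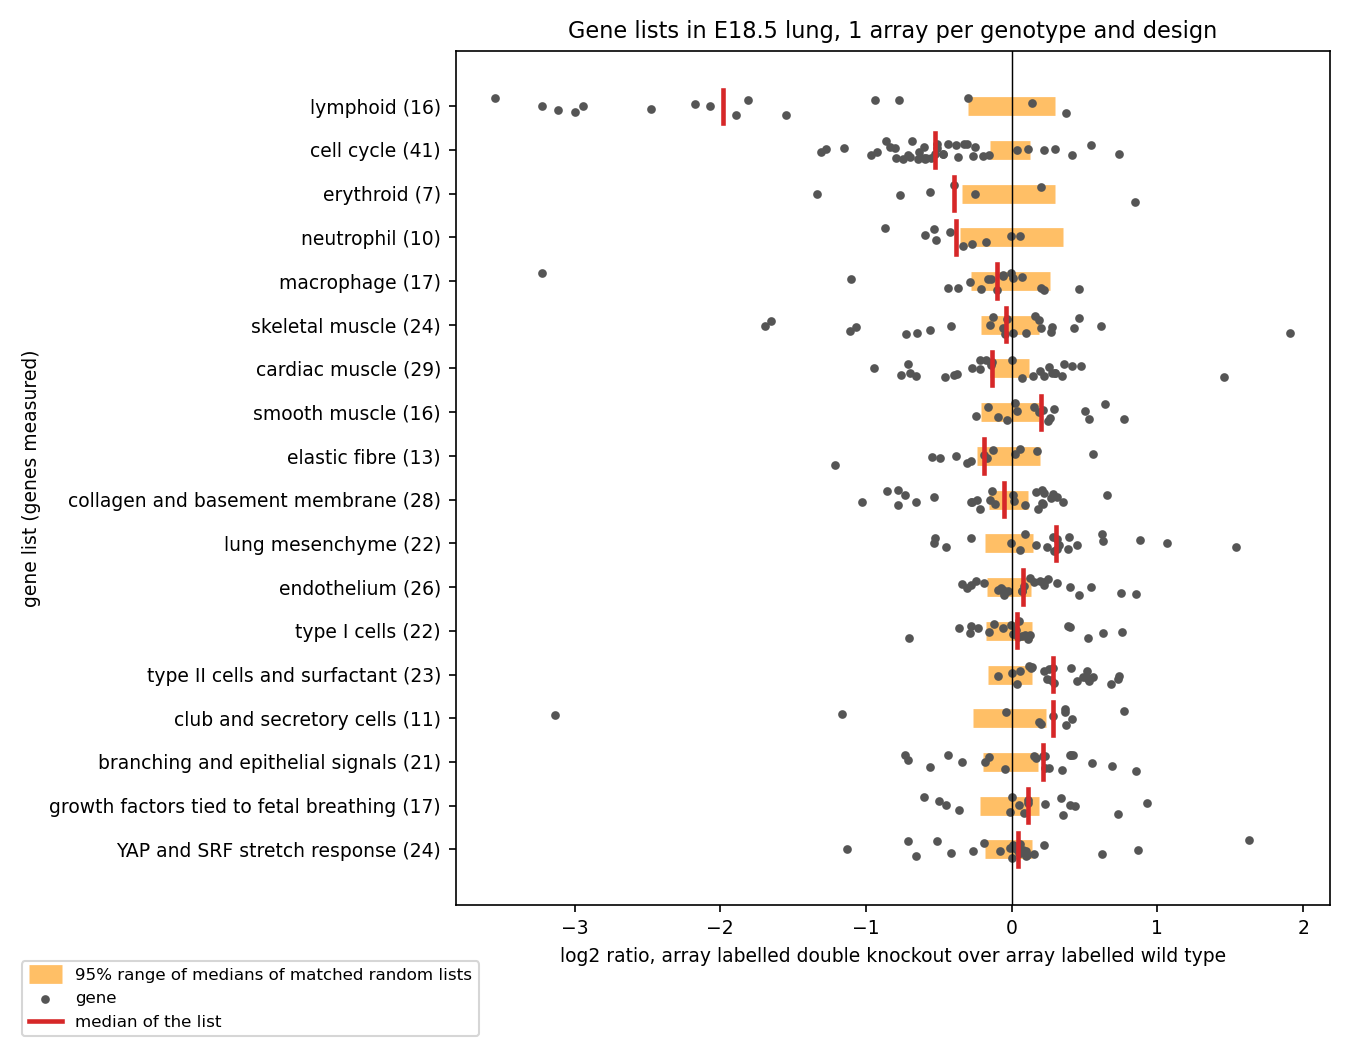
Log2 ratio of the array labelled double knockout over the array labelled wild type for each measured gene (grey points) of the gene lists named on the left axis, with the median of the list (red bar) and the 95% range of medians of random lists matched on size and signal (orange). The lymphoid median of -1.98 and the cell cycle median of -0.53 lie below that range, and the type II and mesenchyme medians of 0.28 and 0.30 above it.

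Of the 37 lists with at least 3 measured genes, 9 had medians outside the 95% range of random lists, 5 above and 4 below, where 1.85 would fall outside by chance. The random lists ignore that genes of a group vary together and were not matched on design. The ranges therefore describe these arrays and are no test between genotypes.

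Across all 12559 genes measured, 483 were at least 2-fold higher and 457 at least 2-fold lower in the arrays labelled double knockout. The counts were 157 and 163 of 9515 genes with both designs on 1 scale, where the filter and floor of MOE430A applied to both, and 135 and 136 of 7658 genes on MOE430A alone. Simulated pairs of arrays that differed by noise alone gave up to 412 and 401 in the setting used. That noise was taken from pairs of probe sets of 1 gene and includes real differences between them. Most single genes of this size therefore cannot be told from noise of that kind. Among genes with high signal on MOE430A, 23 were at least 2-fold higher and 48 at least 2-fold lower, and on MOE430B 104 and 100. A second probe set of the same gene on MOE430A passed 1.5-fold in the same direction for 19 of 25 lower genes (76.0%, exact 95% interval 54.9% to 90.6%) and for 4 of 17 higher genes (23.5%, 6.81% to 49.9%). On MOE430B it did so for 17 of 47 lower genes (36.2%, 22.7% to 51.5%) and for 11 of 35 higher genes (31.4%, 16.9% to 49.3%).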

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

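The tests in this part were all chosen after the results were seen.

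Control probe sets outside the gene comparison held a signal that differed between the labels. The 3 probe sets of 18S ribosomal RNA had a median ratio of 3.93-fold higher in the array labelled double knockout on MOE430A (3.03 to 4.19) and 3.15-fold higher on MOE430B (2.18 to 3.40). The 18 hybridization spikes had medians of 1.47 and 1.31. The 3' to 5' ratios of Gapdh were 0.79 and 0.85 on MOE430A, and 0.75 and 0.81 on MOE430B, and those of actin 1.01 and 1.03 on MOE430A and 1.06 and 1.01 on MOE430B, in the order wild type, double knockout.

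Lymphoid genes were lower in the arrays labelled double knockout. Among them were genes of T cell precursors, Rag1 (at least 11.7-fold lower), Ptcra (log2 ratio -2.07) and Dntt (-0.77), the last 2 named after their values were seen. An error of the MOE430A arrays alone is argued against by MOE430B, where the lymphoid median was -0.82 over 4 genes, below its random range of -0.54 to 0.56. Thymus tissue taken with the lung labelled wild type may be a source. The 4 passing thymic epithelium genes other than the ones seen first had a median of -0.18, inside the range of -0.58 to 0.59. They were Psmb11 (-0.90), Pax9 (-0.34), Foxn1 (-0.02) and Ccl25, which entered at 0.57 by its probe set on MOE430B. The probe set of Ccl25 on MOE430A was at least 8.61-fold lower. The median turns on which of these is taken, so it decides nothing about thymus tissue. Prss16 and Tbata, seen first, had log2 ratios of -2.76 and -2.04. Thymus tissue therefore cannot be told apart from a change that follows genotype or sex, which 1 sample per genotype leaves open and untested.

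Cell cycle genes were lower in the arrays labelled double knockout. On MOE430B alone their median was -0.22 over 10 genes, inside the random range of -0.37 to 0.25, so an error of the MOE430A arrays alone cannot be told apart from a difference between the samples. Whether dividing thymocytes or fewer dividing lung cells could account for the lower values was not tested, since no profile of thymus was analysed here.

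Type II cell and mesenchyme genes were higher in the arrays labelled double knockout. A smaller lymphoid share would raise every lung cell type alike, and 11 lists of lung cell types (163 genes, pooled median 0.12) moved apart, with a Kruskal-Wallis H of 27.9 against 3.33 to 19.9 in 95% of 10000 random deals of the same genes. This leaves the explanation open, since the deals ignore that genes of a group vary together, which makes their range too narrow, and since it was the second test tried and was set up after the list medians were seen. An error of the MOE430A arrays alone is argued against for mesenchyme genes, whose median on MOE430B was 0.30 over 12 genes, above the random range of -0.31 to 0.18, and stays open for type II genes, with 0.14 over 7 genes inside -0.42 to 0.26. A biological difference by genotype, by sex or by exact stage of the embryos remains untested with 1 sample per genotype.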

How the results depend on the processing

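No paired analysis was possible because each genotype had 1 array per design, which also left no replicate to leave out and no other split of the samples. A gene's value is called the same when it moved by less than 0.245, the SD of 1 log2 ratio over shared probe sets, which is smaller than the spread between different probe sets of a gene. A list median is called the same when it moved by less than the SD of the medians of its matched random lists (0.068 to 0.307, median 0.104), a rule set after the values were seen in place of 0.245, which is too wide for medians. The cause was not tested for any value below, except that single designs, stricter filters and higher floors leave fewer genes or compress dim ones by construction. Placing both designs on 1 scale was chosen after the data were seen.

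The counts of genes at least 2-fold higher and lower, 483 and 457, stayed within 1.5 times in 8 of 12 alternatives, and were 184 and 209 with the floor at the median, 148 and 151 with the filter at the 75th percentile, 135 and 136 on MOE430A alone, and 157 and 163 with both designs on 1 scale. On MOE430A alone noise gave up to 95 and 95. The share of higher among all genes past 2-fold ranged from 46.8% to 53.1%. Myod1, at 1.93, was 3.67 with the floor at the 10th percentile and 0.46 with the floor at the median, and no value was had on MOE430B alone or with the filter at the 75th percentile.

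Of the list medians under alternatives, 398 moved by less than their SD, 42 by more and 2 changed sign after lying outside the random range. On MOE430B alone, branching and epithelial signals changed sign to -0.065 and erythroid genes to 0.12 (2 genes). There the medians were also -0.82 for lymphoid, -0.22 for cell cycle, 0.137 for type II cells, 0.46 for smooth muscle, 0.153 for skeletal muscle, 0.45 for cardiac muscle, -0.22 for type I cells, -0.014 for endothelium, -0.43 for growth factors, -0.216 for p53 and cell death and 0.177 for hypoxia. Lists with 2 genes there had -0.089 (pericytes), 0.21 (neuroendocrine cells), 0.49 (basal epithelium), -0.20 (liver) and -0.32 (immediate early), and the values of single genes stood for neutrophil (-0.005), oxidative phosphorylation (0.76) and ribosomal proteins (0.52). The lymphoid median was -1.36 with the floor at the median, -1.09 without a filter, -2.195 with the filter at the 75th percentile, and -2.173 both on MOE430A alone and without probe sets that may cross-hybridise. Without a filter the medians of neuroendocrine and erythroid lists were 0.00, liver 0.039, mesothelium 0.112, neutrophil -0.153 and cardiac muscle -0.057. Cardiac muscle had -0.065 without probe sets that may cross-hybridise. With the filter at the 75th percentile basal epithelium had 1.01, ciliated cells 0.186, lipid synthesis 0.041, cartilage 0.095 (2 genes) and nerve 0.252 (1 gene). With quantile normalization oxidative phosphorylation had -0.055 and ribosomal proteins -0.025, and with loess -0.067 and -0.047. With the median over probe sets hypoxia had -0.073 and mesothelium -0.300.

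Of the 9 lists outside the random range, all 9 were outside on MOE430A alone and 3 of the 6 with at least 3 genes on MOE430B alone (lymphoid, smooth muscle, mesenchyme). Neutrophil was inside with quantile normalization, club cells with loess, erythroid and neutrophil without a filter and with the filter at the 75th percentile, and branching, neutrophil and smooth muscle without probe sets that may cross-hybridise. Cardiac muscle and elastic fibre lay below the range with quantile normalization, with loess, with the median over probe sets and on MOE430A alone, cardiac muscle also with the filter at the 75th percentile and on 1 scale, and elastic fibre also without a filter. On MOE430B alone cardiac muscle lay above the range and growth factors below it. Basal epithelium lay above with the filter at the 75th percentile and on 1 scale, liver on 1 scale, ribosomal proteins without a filter and with the median over probe sets, and the sex-linked list (4 genes) without a filter, at 1.02 against -0.77 to 0.74. Of the named genes' values, 1664 stayed within the SD and 108 moved. The sign changed in 37 values of 22 genes, none of them past 2-fold as reported, and 1 was past 2-fold after the change, Ptch1 at 1.09 on MOE430B alone.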

Other observations

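Further genes of white blood cells named here were chosen after their values were seen. Trbv1, a variable segment of the T cell receptor beta chain, read 9595 in the array labelled wild type and 225.1 in the array labelled double knockout, at least 33.8-fold lower, but its other passing probe set had a log2 ratio of 0.18. Lat, an adaptor of T cell receptor signalling, was at least 7.86-fold lower. On MOE430A alone, Coro1a, an actin regulator abundant in white blood cells, was 5.19-fold lower and Gzma, a granzyme of cytotoxic cells, 5.55-fold lower. MHC class II genes of the lymphoid list were lower as well, with H2-Aa at -1.81 (at least 11.96-fold lower by its probe set on MOE430B), H2-Ab1 at -1.89 and Cd74 at -1.55, genes that macrophages and dendritic cells also make. Of the B lineage genes, Cd79a had 0.37 and Ighm -0.55 to 0.86 over 3 probe sets.

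Malat1, Mmp2 and Inmt were named after their values were seen. Malat1, a nuclear non-coding RNA, had a log2 ratio of 0.69 by the probe set that represents it, on MOE430B (3273 and 5280), and 0.69 to 3.53 over its 6 passing probe sets. The probe sets of Mmp2, a matrix metalloprotease, read 1.56 and 0.15. Inmt, a methyltransferase abundant in lung, was 2.92-fold higher.

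The remaining lists, of lung cell types, other tissues, metabolism and stress, stayed inside the range of random lists in the setting reported. Under some alternatives basal and squamous epithelium, liver and ribosomal proteins did not. Fat had a median of -0.08, mesothelium -0.11, nerve and glia 0.04, cartilage and bone -0.25, liver 0.31, basal and squamous epithelium 0.17, neuroendocrine cells -0.40, pericytes 0.08 and lymphatic endothelium -0.06. In metabolism and stress, hypoxia and glycolysis had 0.02, glucocorticoid response -0.06, lipid and sterol synthesis -0.09, fluid and ion transport -0.03, p53 and cell death -0.07, immediate early genes -0.06, heat shock and ER stress 0.05, oxidative phosphorylation 0.08 and ribosomal proteins 0.16. Single members still differed, such as Krt4, a keratin of squamous epithelium, at 1.55 (at least 8.90-fold higher by its other probe set), Hmgcs1 and Fdps of sterol synthesis at -0.52 and -0.65, and Ano1, a chloride channel, at -0.77 with its other probe set at 0.26.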
